A study of Homo sapiens with 12 samples.

How the data were processed

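RNA from 12 HAP1 samples was sequenced: wild-type and PBRM1 knockout cells, each untreated or with 50 ng/mL of IFNγ for 5 days, with 3 libraries per group. Per the labels' protocols, the knockout was made in bulk with a guide RNA in HAP1 cells that carry Cas9, under blasticidin and puromycin, and libraries were made with a poly-A mRNA kit. No control guide is named for the wild-type cells, and the labels describe a single cell pool per genotype, so a difference between the genotypes cannot be told from drift between the pools. The deposited files hold raw read counts per gene for each library, and per the submitters' processing notes the tools were FastQC 0.11.3, STAR 2.5.2b, featureCounts 2.0.1, DESeq2 1.34.0 and R 4.1.2 with the hg19 genome build. The gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Counts of genes with near-identical copies, such as the HLA, HSPA1A, HSPA1B, MICA and MICB genes, are therefore uncertain, and no genome coordinates are printed.

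Groups were taken from the labels, and every count column was matched to its sample. The files hold 23228 genes, of which 3565 had no count in any library. The total count per library was 23161444 to 40658522, with 16190 to 17393 genes detected. Genes with few counts were removed with edgeR's filterByExpr, which left 14445 genes holding at least 99.97% of each library's counts. Counting error of genes with 1 to 3 counts in a group is given as an exact 95% interval, and a group without counts was set to a floor of 3 counts over its 3 libraries, which gives a fold as a lower bound. Intervals and floors cover counting error only.

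Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust, in R 4.3.3) in 1 fit of all 12 libraries with 4 group means, so that the groups share an estimate of the spread. The biological coefficient of variation was 7.66%. The 5 comparisons were IFNγ against untreated in each genotype, knockout against wild-type in each treatment, and the difference of the IFNγ responses. The p-values were adjusted by the Benjamini-Hochberg method per comparison at a threshold of 0.05. SE is an approximate error of the log2 fold change, taken as its size over the square root of the F statistic. It can be too small where a group is nearly without counts, as for the largest rises with IFNγ. An exact test of 3 against 3 libraries cannot give a two-sided p below 0.1, so single values were not tested outside the model. Gene lists were tested with camera from limma 3.58.1 on log CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over 95 tests of 19 lists in 5 comparisons. Of 21 lists, the mitochondrial transcripts had no tested gene and the markers of other blood cells only 2, and both were left out of camera.

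The groups, tests, gene lists, named gene rule and most other settings were chosen before the data were examined. Named genes were PBRM1; in each comparison the 8 higher and 8 lower of largest fold change among genes past the threshold, with at least 5 CPM in every library of the higher group and groups that did not overlap; up to 4 members of each list; and a fixed panel of interferon and PBAF genes. From these, 84 genes were described, and some that the rule names are not reported here. Some of the 84 are also given in comparisons for which the rule did not name them, chosen after their values were seen. Genes whose calls changed when 1 library was left out were mostly dropped after their values were seen.

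The other settings were DESeq2 size factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the compared groups in the fit, a change of at least 2-fold, an estimated correlation in camera, and leaving out each library in turn. Plain library sizes, offsets for GC content and leaving out the long arm of chromosome 1 were added after seeing the data. GC content and length came from a reference of a later build by gene symbol, which matched 95.4% of the tested genes. Chromosome arms were found the same way for 96.2%.

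The edgeR step was tested on simulated counts with the real library sizes and each gene's mean over all 12 libraries. Of 14445 genes 200 were changed, in 1 group. In IFNγ against untreated in wild-type cells it recovered 92.4% of 4-fold, 94.0% of 2-fold and 82.1% of 1.5-fold changes, with 7.25% false calls. For the difference of responses it recovered 93.9%, 82.1% and 59.7%, with 3.09% false calls. The simulation held no GC trend and few changed genes, while the real comparisons called between 30.6% and 70.8% of genes. These rates therefore check the code and do not give the error rates of the real comparisons. No duplicate libraries were found when replicates were compared by their counts.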

Results

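RNA was measured by poly-A RNA-seq in HAP1, a near-haploid human leukaemia line, in which PBRM1 was either left intact or knocked out in bulk with a guide RNA. PBRM1 encodes a subunit of the PBAF form of the SWI/SNF chromatin remodelling complex. Both genotypes were kept for 5 days without treatment or with 50 ng/mL of interferon gamma (IFNγ), a cytokine that signals through JAK kinases. The design gave 4 groups of 3 libraries, and the total count per library lay between 23161444 and 40658522. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The first principal component held 69.6% of the variance and parted treated from untreated libraries. The second held 19.2% and parted the genotypes. The deviation of each library from the other 2 of its group was compared with GC content by Spearman's rho across genes (not independent replicates). With IFNγ rho was 0.685, -0.795 and 0.676 for PBRM1 knockout replicates 1 to 3 and 0.439, 0.114 and -0.457 for wild-type. Values within a group are tied, since each library is part of the reference of the other 2, so they are not separate trends. In untreated libraries rho lay between -0.280 and 0.167. With transcript length it was -0.450 in knockout untreated replicate 2. Knockout IFNγ replicate 2 deviated most, and the counts of called genes are also given without it.

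PBRM1 RNA was lower in the knockout in every library. In untreated cells it stood at 167 ± 7.58 CPM (counts scaled to library size by TMM; SD, n = 3) in wild-type and 46.2 ± 3.77 (SD, n = 3) in knockout libraries, or 27.7% of the wild-type level. With IFNγ it stood at 130 ± 2.07 in wild-type and 59.6 ± 6.83 in knockout libraries, or 46.0%. The log2 fold change of knockout against wild-type was -1.85 (SE 0.09) in untreated cells and -1.12 (SE 0.08) with IFNγ, with edgeR quasi-likelihood Benjamini-Hochberg adjusted p-values of 2.09e-11 and 8.92e-09. With IFNγ, PBRM1 fell by 0.36 on the log2 scale in wild-type cells and rose by 0.36 in knockout cells, or by 0.22 with GC offsets, which were chosen after seeing the data. The difference between these responses was 0.73 (SE 0.12, edgeR adjusted p = 2.07e-04).

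**Figure D1:**
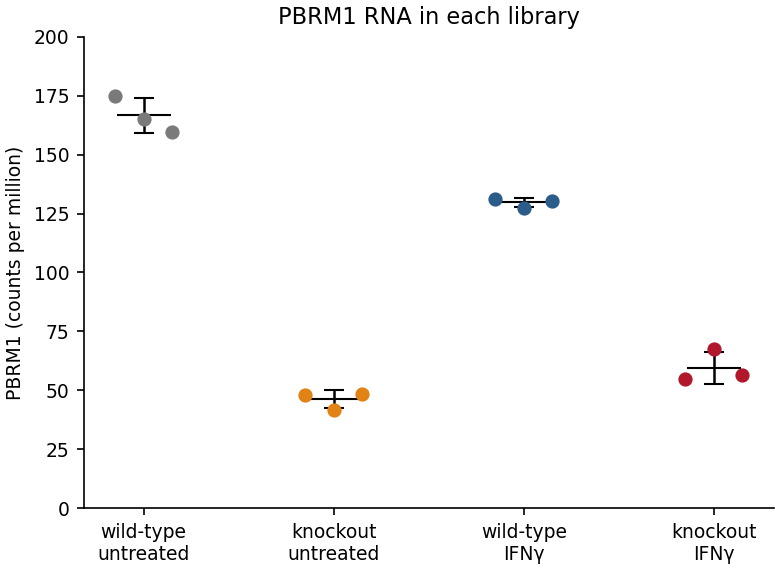
PBRM1 RNA in CPM (vertical axis) in each of the 12 libraries, by group; points are libraries, bars the mean and whiskers the SD of 3 libraries. The 6 knockout libraries lie between 41.8 and 67.4, below the 6 wild-type libraries, which lie between 127 and 175.

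The first comparison asked which genes IFNγ changed in wild-type cells. The chemokine CXCL10 had no count in the untreated libraries and 3411 ± 252 CPM (SD, n = 3) with IFNγ, at least 95604-fold higher against a floor of 3 counts over the group. The guanylate-binding protein gene GBP5 rose from 3 counts in the 3 untreated libraries, a ratio of 34370 (95% counting interval 11761 to 166667, which covers counting error only). The transcription factor gene IRF1 rose by a log2 fold change of 6.20 (SE 0.14). The tryptophan-degrading enzyme gene IDO1 rose by 11.54 (SE 0.17), and the checkpoint ligand gene CD274 by 6.44 (SE 0.20). Both had few untreated counts, so these SE are likely too small. For IDO1 the difference of the responses between the genotypes had an SE of 0.47. In all, 4971 of 14445 genes were higher and 5259 lower at an edgeR adjusted p under 0.05, and without knockout IFNγ replicate 2, which shares the fit, the counts were 5635 and 5690.

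Of the 42 tested members of the interferon gamma response list, 39 rose and 2 fell, with a median log2 fold change of 4.77. All 49 tested type I interferon stimulated genes rose (median 4.27), among them IFI27 by 8.95 (SE 0.16), ISG15 by 4.42 (SE 0.15) and IFIT3 by 8.84 (SE 0.14). Of 22 genes of MHC class I antigen presentation, 20 rose and 1 fell (median 2.64), with HLA-B at 3.25, B2M at 2.67, the peptide transporter gene TAP1 at 4.49 and the class I transactivator gene NLRC5 at 1.24. HLA-B shares sequence with other HLA genes and its count is uncertain. Of 14 genes of MHC class II presentation, 11 rose and 1 fell (median 4.66). The class II transactivator gene CIITA went from 1 to 841 counts and the invariant chain gene CD74 was at least 1052-fold higher. These 4 lists passed the camera test, with adjusted p-values of 1.47e-19, 2.33e-20, 7.61e-10 and 5.74e-05, and kept it with an estimated inter-gene correlation (adjusted p = 0.00543, 0.00528, 0.0435 and 0.0356). MX1, an antiviral gene of the fixed panel, had 33 counts over all libraries and was not tested.

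Other groups moved in wild-type cells as well. Of 21 NF-κB and inflammatory genes 19 rose and none fell (median 1.68, camera adjusted p = 1.33e-07), with RELB up by 4.63 and the NF-κB inhibitor gene TNFAIP3 by 2.91. Of 33 genes of the integrated stress response 31 rose (median 1.68, camera adjusted p = 3.22e-15), including the stress effector genes DDIT3 by 3.95 and CHAC1 by 4.16. All 23 genes of cholesterol biosynthesis fell (median -1.73, camera adjusted p = 7.94e-11), with HMGCS1, an early enzyme of the pathway, at -2.90 (SE 0.08) and INSIG1, a sterol-regulated inhibitor of it, at -2.83 (SE 0.10). Of 22 cell death genes 17 rose and 2 fell (median 0.70, camera adjusted p = 8.58e-05), with the death receptor gene FAS up by 4.38. These 4 lists also passed with an estimated correlation (adjusted p = 0.0305, 0.0305, 0.0103 and 0.0187).

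Of 15 checkpoint and NK cell ligand genes 12 rose (median 1.34, camera adjusted p = 5.78e-05), of 24 immediate early and heat shock genes 16 rose and 5 fell (median 0.91, 0.0055), and of 33 receptor and JAK-STAT genes 19 rose and 7 fell (median 0.41, 0.0161). With an estimated correlation these 3 lists were not past the threshold (adjusted p = 0.0716, 0.206 and 0.0573). Among the JAK-STAT genes, SOCS3, a feedback inhibitor, rose by 3.46 and IFNGR1, a subunit of the receptor, by 0.56. No direction passed the camera test in wild-type cells for SWI/SNF subunits (7 higher, 9 lower of 26), DNA replication (13 and 21 of 45), mitosis (7 and 19 of 40), p53 targets (9 and 8 of 24), hypoxia and glycolysis (11 and 25 of 38), innate sensing (6 and 2 of 11), adhesion and matrix (16 and 16 of 42) or epithelial and fibroblast markers (4 and 5 of 9). The smallest adjusted p among them was 0.0591. Innate sensing passed without wild-type untreated replicate 1 (adjusted p = 0.0496), and hypoxia and glycolysis without a filter on low counts (0.0392). The adhesion list had a median of -0.08, a mean of 0.37 and a test direction of higher. MOBP, a gene best known from myelin, fell from 59.0 to 1.0 CPM. Of 26 markers of other blood cells 25 stayed under 1 CPM in all groups, and the 13 mitochondrial transcripts of the last list were not analysed here.

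IFNγ was then compared with no treatment in knockout cells. CXCL10 rose from 3 counts in the untreated group to 775 ± 110 CPM (SD, n = 3), a ratio of 24693 (95% counting interval 8449 to 119743). IRF1 rose by 5.09 (SE 0.13), IDO1 by 9.69 (SE 0.15), B2M by 3.25 (SE 0.10) and NLRC5 by 2.28 (SE 0.10). Here 5035 genes were higher and 4916 lower at an edgeR adjusted p under 0.05, and without knockout IFNγ replicate 2 the counts were 5320 and 5374. Of those called in both genotypes, 3815 were higher in both, where independent lists would share 1733, and 3780 were lower in both, against 1790. Another 174 were higher in wild-type and lower in knockout cells, and 187 the reverse. These contrasts share no libraries, and across genes, which are not independent, their fold changes correlated with Pearson's r = 0.879 and Spearman's rho = 0.8.

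In knockout cells 39 interferon gamma response genes rose and 3 fell (median 5.01), 44 type I genes rose and 3 fell (2.99), 21 class I genes rose and 1 fell (2.75), and 11 class II genes rose and 2 fell (4.57, or 4.39 with genes of few counts at their bound). Their camera adjusted p-values were 3.12e-18, 3.32e-15, 6.53e-11 and 1.88e-04, and 0.00543, 0.00543, 0.0356 and 0.0438 with an estimated correlation. Of the integrated stress response genes 32 rose (median 2.13) and all 23 cholesterol genes fell (median -2.20), with camera adjusted p-values of 3.46e-17 and 3.54e-13, or 0.0282 and 0.00611 with an estimated correlation. DNA replication genes fell, 34 of 45 against 5 higher (median -0.50, camera adjusted p = 1.25e-05, 0.0305 with an estimated correlation), with LIG1, a DNA ligase gene, at -1.69. NF-κB genes (17 higher, 1 lower), cell death genes (12 and 4), checkpoint and NK ligands (10 and 3) and hypoxia and glycolysis (10 and 25) passed camera at adjusted p = 2.09e-04, 0.0217, 0.0055 and 0.00282. With an estimated correlation they were not past the threshold (adjusted p = 0.0741, 0.0724, 0.174 and 0.408), and with GC offsets, chosen after seeing the data, the cell death list was not either (adjusted p = 0.0665). The median of the checkpoint and NK ligands was 1.82, or 1.04 without a filter on low counts. The lists of JAK-STAT components (18 higher, 8 lower), SWI/SNF subunits (10 and 7), mitosis (16 and 10), p53 targets (10 and 8), immediate early and heat shock genes (12 and 9), adhesion (16 and 14), innate sensing (6 and 2) and epithelial markers (4 and 5) did not pass, the smallest adjusted p being 0.0591. Innate sensing passed with GC offsets (adjusted p = 0.0486), plain library sizes (0.0447) and no filter on low counts (0.0274), and the JAK-STAT list without the long arm of chromosome 1 (0.0499). The SWI/SNF list had a median of 0.11 and a mean of -0.04, and the epithelial list -0.55 and 0.07.

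**Figure D2:**
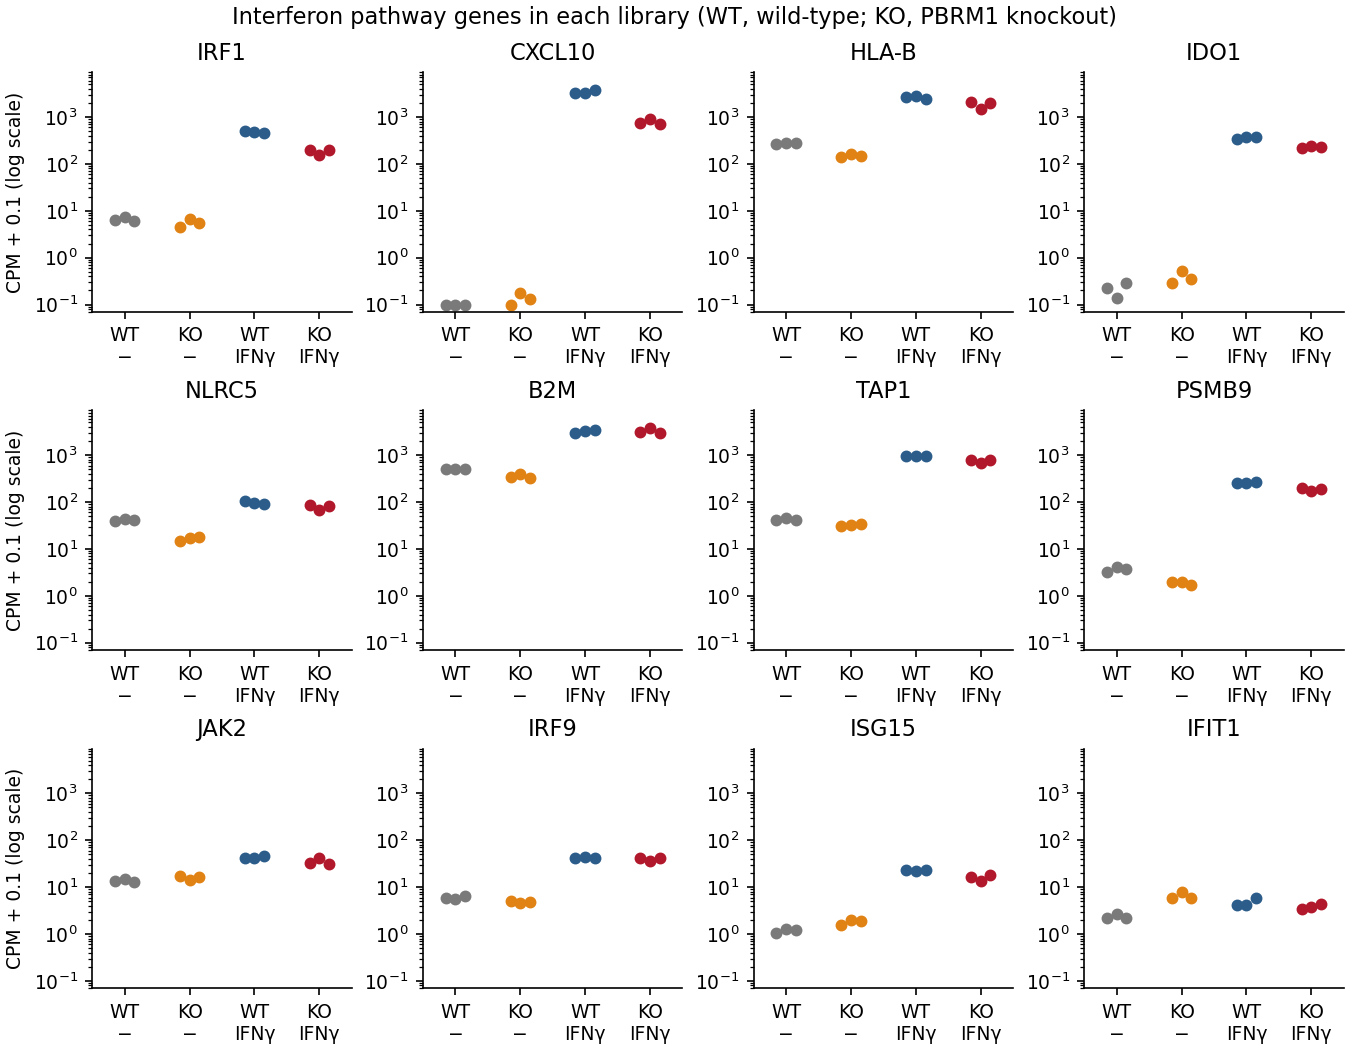
CPM plus 0.1 on a log axis (vertical) for 12 interferon pathway genes of the fixed panel in each library, by genotype and treatment; each point is 1 library. CXCL10 stands at 3411 CPM on average in treated wild-type and 775 in treated knockout libraries, and IRF1 at 476 and 185.

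Knockout and wild-type cells were next compared without treatment. The sorting nexin gene SNX19 stood at 0.350 ± 0.0742 CPM in wild-type and 43.1 ± 1.15 in knockout libraries (SD, n = 3), and SPARC, a matrix protein gene, was higher by a log2 fold change of 3.96 (SE 0.19). BNC1 went from 2 counts in the wild-type group to 585, a ratio of 253 (95% counting interval 69.8 to 2095). ZCCHC12 fell from 517 ± 15.0 to 74.3 ± 2.84 CPM, the homeobox gene ESX1 had a log2 fold change of -2.76 (SE 0.10), CPS1, the first enzyme of the urea cycle, -2.60 (SE 0.10), and the cyclin gene CCND2 -2.21 (SE 0.07). In all, 2673 genes were higher and 2830 lower at an edgeR adjusted p under 0.05. With plain library sizes, chosen after seeing the data, the split was 3573 to 2206, and without knockout IFNγ replicate 2 it was 3774 to 3912.

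Type I interferon stimulated genes were higher in untreated knockout cells, 20 of 49 against 10 lower (median 0.44, camera adjusted p = 0.0153). The list did not pass with an estimated correlation (adjusted p = 0.155) or plain library sizes (0.0592), and its median was 0.23 without knockout untreated replicate 2 (0.035). IFIT3 was higher by 2.96 (SE 0.22), OAS2 by 3.42 (SE 0.49) and CMPK2 by 2.70 (SE 0.29), while SAMD9 was lower at -3.48 (SE 0.60); all 4 lay under 2 CPM in both groups. Genes of MHC class I presentation were lower, 10 of 22 against 2 higher (median -0.33, camera adjusted p = 0.0028), with NLRC5 at -1.32 (SE 0.10), the immunoproteasome gene PSMB8 at -1.54 (SE 0.09), HLA-B at -0.86 (SE 0.10) and B2M at -0.53 (SE 0.09). The class I list did not pass with an estimated correlation (adjusted p = 0.24). Of 11 innate sensing genes 5 were lower (median -0.26, camera adjusted p = 0.0132, 0.0701 with an estimated correlation), among them the DNA sensor gene IFI16 at -1.90 (SE 0.07). The median was -0.17 without a filter on low counts or with one of at least 1 CPM in 3 libraries. The interferon gamma response list had 10 genes higher and 6 lower (median 0.01, camera adjusted p = 0.59). The other lists did not pass in untreated cells. Cholesterol biosynthesis passed without the long arm of chromosome 1 (median 0.21, adjusted p = 0.046). Closest was hypoxia and glycolysis, with 15 genes higher and 4 lower (median 0.10, camera adjusted p = 0.0524). It passed at 0.0345 without wild-type untreated replicate 2, at 0.0428 and 0.0159 without knockout untreated replicate 1 and 3, and at 0.0480 without wild-type IFNγ replicate 2. It also passed with DESeq2 size factors (0.0499), no filter on low counts (0.0189), a filter of 1 CPM (0.0340), plain library sizes (0.0484), GC offsets (0.0455) and without the long arm of chromosome 1 (0.0499), but not with an estimated correlation (0.639). Among its members BNIP3, a hypoxia-responsive mitophagy gene, was higher by 1.2, and EGLN3 by 1.28. Of the adhesion list (15 higher, 12 lower) the matrix gene FN1 was higher by 1.58. The medians of the cell death (0.04) and NF-κB lists (-0.03) had means of the other sign, -0.09 and 0.43.

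Genes on the long arm of chromosome 1 were lower together in knockout cells. Of its 616 tested genes 472 were lower and 22 higher without treatment, with a median log2 fold change of -0.54, against 0.03 on the short arm and -0.00 on the other chromosomes. With IFNγ 393 were lower and 41 higher, with a median of -0.41. IFI16 lies on this arm, with 2 other members of the innate sensing list, and without the arm's genes that list was not past the threshold (median -0.18, camera adjusted p = 0.0981). Of the interferon gamma response, type I and MHC class I lists, 0, 1 and 0 tested members lie there.

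**Figure D3:**
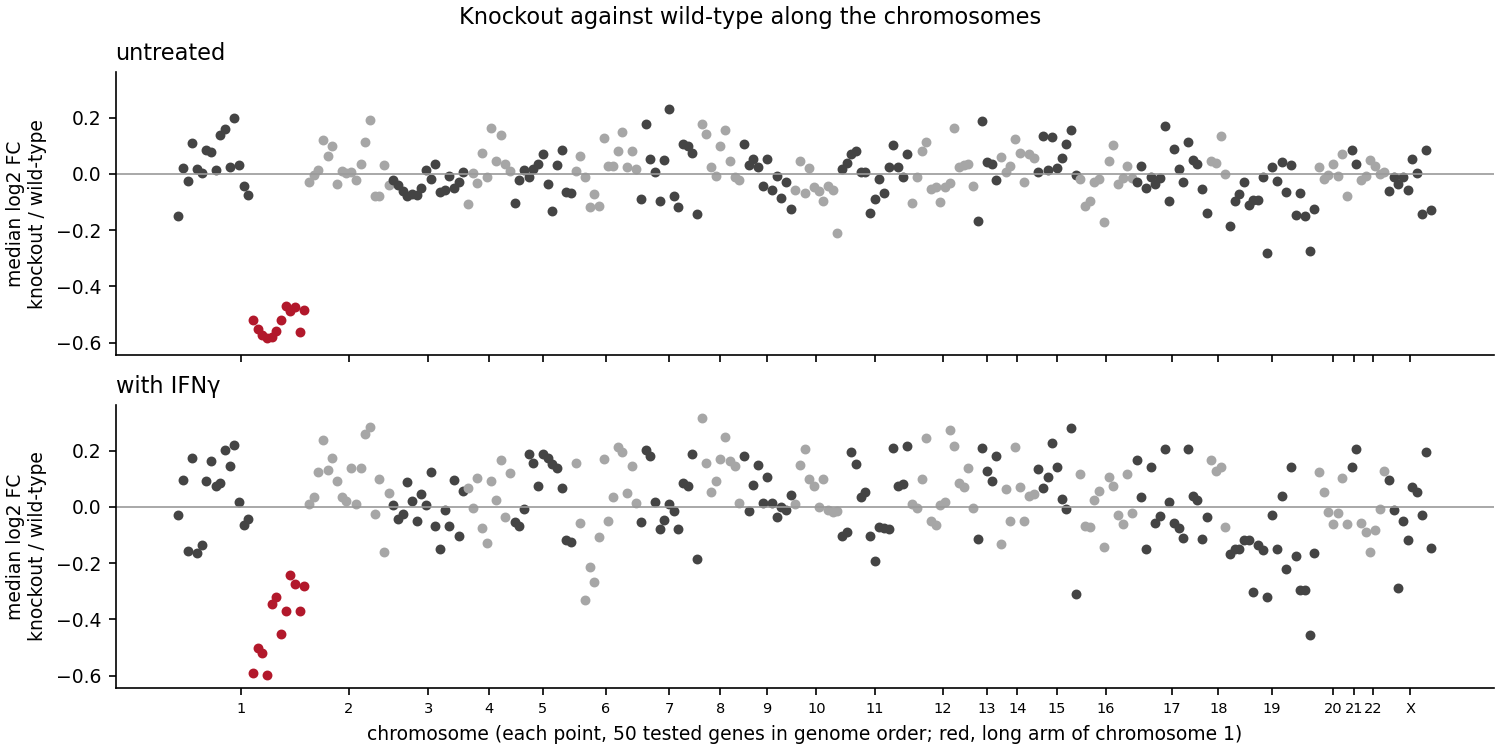
Median log2 fold change of knockout against wild-type (vertical axis) in 269 consecutive bins of 50 tested genes in genome order (horizontal axis, by chromosome), without treatment above and with IFNγ below; each point is 1 bin. The 12 bins on the long arm of chromosome 1, in red, lie between -0.58 and -0.47 without treatment, and the 256 bins wholly off the arm between -0.28 and 0.23. With IFNγ the ranges overlap, from -0.60 to -0.24 on the arm and from -0.46 to 0.32 off it.

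With IFNγ, interferon targets were lower in knockout than in wild-type cells. CXCL10 was lower at -2.14 (SE 0.10), UBD, a ubiquitin-like gene, at -1.79 (SE 0.09), IRF1 at -1.36 (SE 0.11) and IDO1 at -0.65 (SE 0.08). B2M (0.06, SE 0.09) and CD274 (-0.05, SE 0.10) did not pass the test. Of the interferon gamma response list 27 of 42 genes were lower and 7 higher (median -0.46, camera adjusted p = 0.00141), of the type I list 34 of 49 lower and 3 higher (-0.45, 4.86e-06), of class I 15 of 22 lower and 3 higher (-0.33, 0.0231) and of class II 10 of 14 lower and 1 higher (-0.78, 0.00407). With an estimated correlation the type I list passed (adjusted p = 0.0305), and the others did not (adjusted p = 0.114, 0.395 and 0.0962). With GC offsets the class I median was -0.24 (camera adjusted p = 0.075). In all, 4123 genes were higher and 3814 lower at an edgeR adjusted p under 0.05, and without knockout IFNγ replicate 2 the counts were 4391 and 4490.

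Members of other lists were lower as well in treated knockout cells. Of 21 NF-κB genes 17 were lower and 1 higher (median -0.67, camera adjusted p = 5.51e-05, or 0.0582 with an estimated correlation), with TNFAIP3 at -2.49 (62.3 against 11.1 CPM) and RELB at -2.04. Of 24 immediate early and heat shock genes 14 were lower and 3 higher (median -0.69, camera adjusted p = 0.00222, or 0.167 with an estimated correlation), with the chaperone genes HSPA1A at -2.25, its near-identical and so uncertain neighbour HSPA1B at -2.12, and DNAJB1 at -1.65, while EGR1, a growth factor response gene, was higher by 4.01 (SE 0.13). DNA replication genes were lower, 29 of 45 against 5 (median -0.32, camera adjusted p = 5.78e-05, or 0.0361 with an estimated correlation), with the licensing genes CDT1 at -1.12 and ORC1 at -1.0. Lists of cholesterol biosynthesis (15 lower, 1 higher), cell death (13 and 3) and checkpoint and NK ligands (7 and 0) had camera adjusted p-values of 0.00368, 0.00863 and 0.00927, and did not pass with an estimated correlation (adjusted p = 0.106, 0.0515 and 0.2). Among the last were MICB at -1.42 and MICA at -1.20, which share sequence and are uncertain. The median of that list was -0.29, or -0.19 without knockout IFNγ replicate 2. The integrated stress response was higher, 21 of 33 against 3 (median 0.29, camera adjusted p = 0.00282, or 0.286 with an estimated correlation), with the cystine transporter gene SLC7A11 up by 1.78 and the serine synthesis gene PSAT1 by 0.85.

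The innate sensing list (2 higher, 7 lower of 11) had a camera adjusted p of 0.0568 in treated cells. It passed at 0.0482 without knockout untreated replicate 3, at 0.0477 without wild-type IFNγ replicate 1 and at 0.0494 without knockout IFNγ replicate 2. Each was left out alone, and with GC offsets the list passed at 0.0452. The lists of JAK-STAT components (9 higher, 14 lower), SWI/SNF subunits (7 and 8), mitosis (13 and 6), p53 targets (10 and 6), hypoxia (10 and 14), adhesion (19 and 9) and epithelial markers (3 and 4) did not pass. The adhesion list passed without a filter on low counts (adjusted p = 0.0392). The p53 list had a median of 0.08 and a mean of -0.01.

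Outside the lists, SNX19 was higher by 9.01 (SE 0.18), the RNA-binding protein gene LIN28A by 6.81 (SE 0.25), THBS1, a matrix protein gene, by 5.05 (SE 0.11) and the myosin gene MYH15 by 4.26 (SE 0.10). The genes BCL2L14 (-2.78, SE 0.11), NGFR (-2.76, SE 0.16) and MYBPC1 (-2.73, SE 0.13) were lower. Of the SWI/SNF subunits SMARCA2, an ATPase of the complex, was lower at -1.86 (SE 0.09) and BRD7, a PBAF subunit, higher by 0.63 (SE 0.07), while the ATPase gene SMARCA4 did not pass (-0.06, SE 0.10). Genes called for the knockout in both treatments numbered 1540 higher in both (763 for independent lists) and 1672 lower in both (747), with 258 higher without treatment and lower with it, and 200 the reverse. The fold changes of the 2 contrasts, which share no libraries, correlated across genes with Pearson's r = 0.594 and Spearman's rho = 0.493.

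**Figure D4:**
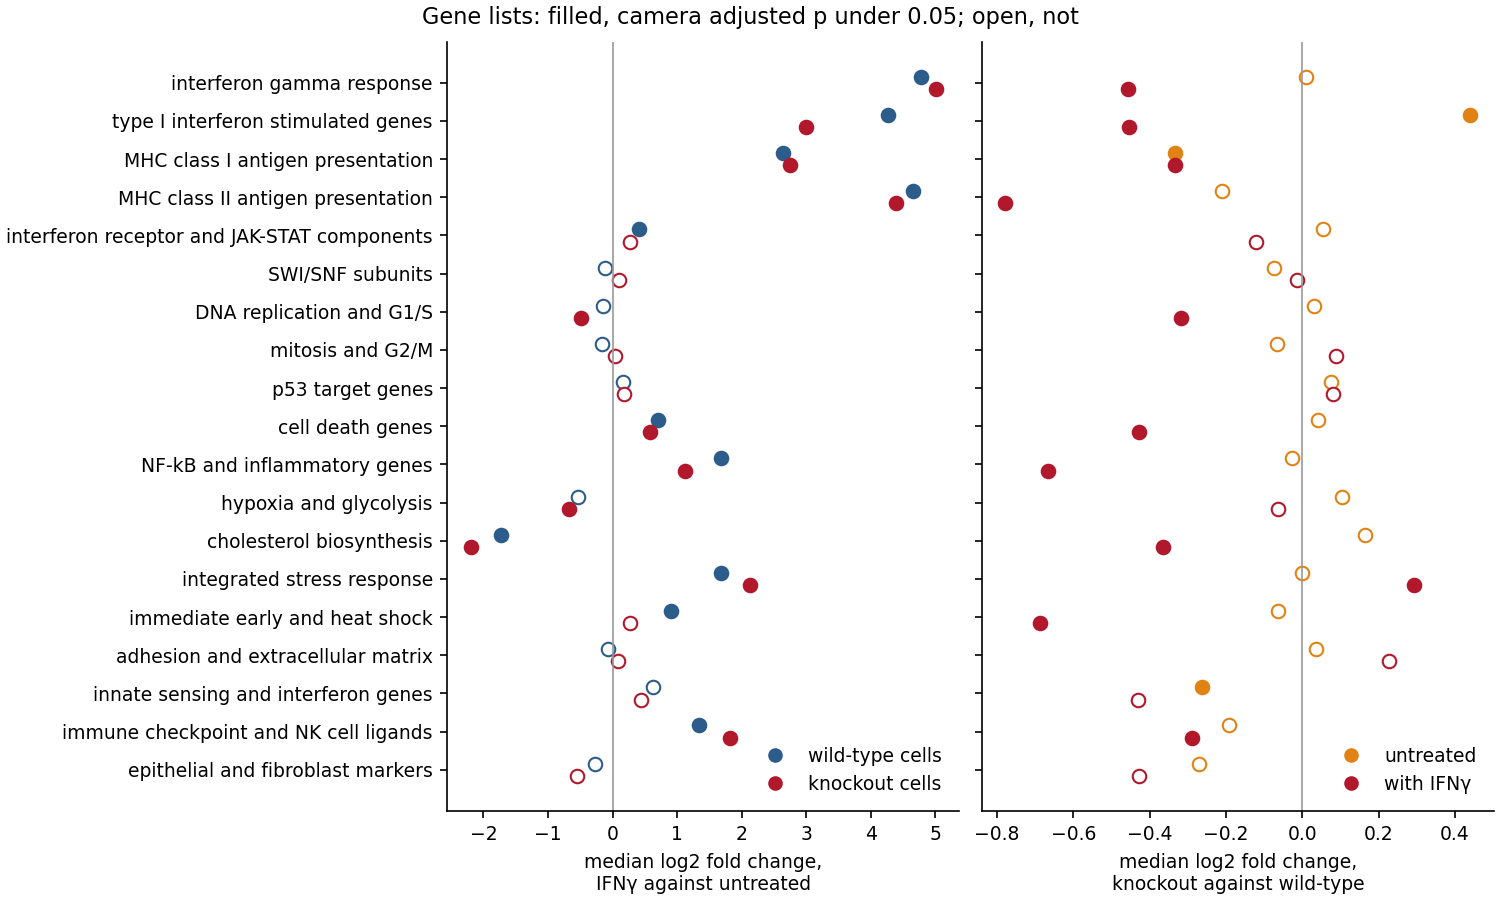
Median log2 fold change (horizontal axis) of each of 19 gene lists (vertical axis), for IFNγ against untreated on the left and knockout against wild-type on the right; filled points passed camera at an adjusted p under 0.05, open points did not. The type I interferon list stands at 4.27 in wild-type and 2.99 in knockout cells on the left, and at 0.44 without treatment and -0.45 with IFNγ on the right; the class II list in knockout cells is drawn at 4.39, with genes of few counts at their bound.

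The difference of the IFNγ response between the genotypes was tested as an interaction. The type I interferon list responded less in knockout cells, with 22 of 49 genes past the threshold in that direction and 3 in the other (median difference -0.83, camera adjusted p = 2.68e-09, 0.0142 with an estimated correlation). IFIT1 rose by 1.03 in wild-type cells and fell by 0.73 in knockout cells, a difference of -1.76 (SE 0.24). Over the 42 members with more than 3 counts in every group the median was -0.72. The interferon gamma response list had 8 genes lower and 2 higher (median -0.45, camera adjusted p = 4.61e-05, 0.0573 with an estimated correlation), and its median was -0.24 over the 28 members with more counts. NF-κB genes (0 higher, 13 lower, median -0.64, 8.86e-08), DNA replication (2 and 22, -0.29, 1.57e-06), cholesterol biosynthesis (0 and 12, -0.33, 1.85e-05) and cell death genes (2 and 9, -0.21, 0.00282) also responded lower, and kept camera with an estimated correlation (adjusted p = 0.0305, 0.0282, 0.0356 and 0.0356). The cell death median was -0.32 without wild-type IFNγ replicate 2, -0.35 without knockout IFNγ replicate 2 and -0.33 with plain library sizes. Of MHC class I genes 6 responded more and 4 less, with no common direction by camera (median 0.12, adjusted p = 0.611), while NLRC5 rose more in knockout cells by 1.04 (SE 0.13) and B2M by 0.59 (SE 0.13). In knockout cells the integrated stress response list responded higher (15 genes against 2, median 0.30, camera adjusted p = 0.00314), and hypoxia (2 against 15, -0.23, 3.24e-04) and immediate early and heat shock genes (5 against 12, -0.45, 0.00295) lower. These 3 lists were not past the threshold with an estimated correlation (adjusted p = 0.29, 0.312 and 0.174), and the integrated stress response median was 0.18 with plain library sizes.

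Among single genes, the myosin gene MYH15 differed most in the higher direction of those named here, by 4.96 (SE 0.16), and BCL2L14 by -3.71 (SE 0.31) in the lower. In all, 2417 genes responded higher and 1996 lower at an edgeR adjusted p under 0.05. With plain library sizes these were 1514 and 2781, with GC offsets 3416 and 3083, without knockout IFNγ replicate 2 they were 3162 and 2972, and without wild-type IFNγ replicate 1 or 2 the number higher was 1563 or 1533. The mitosis list (11 higher, 2 lower, median 0.14, camera adjusted p = 0.023) had an adjusted p of 0.455 with an estimated correlation. It was also lost without knockout untreated replicate 3 (adjusted p = 0.0562), wild-type IFNγ replicate 1 (0.0632) or 2 (0.0570), or knockout IFNγ replicate 2 (0.109), with medians between 0.06 and 0.12, and with a filter of 1 CPM (median 0.09, adjusted p = 0.0541), GC offsets (0.08, 0.325), plain library sizes (0.03, 0.0833) or without the long arm of chromosome 1 (0.07, 0.0999). The checkpoint and NK ligand list (1 higher, 4 lower, median -0.06, 0.0452) had an adjusted p of 0.317 with an estimated correlation, and was lost without knockout untreated replicate 1 (0.0635), wild-type IFNγ replicate 2 (0.0808) or knockout IFNγ replicate 2 (0.210), with GC offsets (0.123), plain library sizes (0.0615) or without the long arm of chromosome 1 (0.0535), and over its 14 members with more counts (0.1). Its median was -0.10 without knockout untreated replicate 1 or wild-type IFNγ replicate 1 or 3, -0.15 without knockout IFNγ replicate 1 or 3, -0.17 with plain library sizes, -0.11 with a filter of 1 CPM or without the arm, and -0.10 without a filter. The MHC class II list (median -0.18, 0.0217, or 0.161 with an estimated correlation) was lost without knockout IFNγ replicate 2 (0.0772), with GC offsets (0.0556), plain library sizes (median -0.29, 0.0590) or without the arm (0.09), and over its 9 members with more counts (0.191). Its median was -0.27 without knockout IFNγ replicate 3. The lists of JAK-STAT components (3 higher, 8 lower), SWI/SNF subunits (6 and 3), p53 targets (6 and 6), adhesion (8 and 7), innate sensing (3 and 2) and epithelial markers (0 and 2) did not pass.

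Over members of the lists fixed before the data were examined, the counts adjusted over the list alone equalled those over all genes in 71 of 100 lists times comparisons, and differed by at most 4 genes in the others. For the type I list they were 49 higher in wild-type cells with IFNγ, 34 lower and 3 higher for the treated knockout, and 26 lower and 3 higher for the difference of responses. For the interferon gamma response list they were 39 higher and 3 lower, 27 lower and 7 higher, and 8 lower and 2 higher. For class I they were 20 higher and 1 lower, 15 lower and 3 higher, and 4 lower and 7 higher.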

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

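The tests of unedited cells, of the share of responding cells, of library size, of the response of 1 library and of leaving out 1 library were chosen after the result was seen, and the splits and the GC test before. The scaling tests were set before their results were seen, but 1 of their 2 scalings, plain library sizes, was chosen after seeing the data. The genes and lists below were picked out because their IFNγ response differed between the genotypes in the edgeR interaction or camera test. Of 84 described genes, 62 passed with more than 3 counts in every group, 21 higher and 41 lower in knockout cells. These genes were picked by fold change and list, and their balance does not stand for all genes, of which 2417 were higher and 1996 lower. Unless said otherwise, values are log2 differences, knockout response minus wild-type response, and list medians are over members with more than 3 counts in every group.

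Interferon and antigen presentation genes moved both ways. Lower in knockout cells were the responses of IRF1 (-1.12), IDO1 (-1.85), SOCS3 (-0.85), ISG15 (-1.15), IFIT1 (-1.76), IFIT3 (-3.22), OAS2 (-3.54) and CMPK2 (-2.92). Higher were WARS (1.18), SAMD9 (3.03), NLRC5 (1.04), PSMB8 (0.87), B2M (0.59) and IFI16 (1.25), which lies on the long arm of chromosome 1, while IRF3 was lower (-0.65). A difference of responses is not a difference of treated levels. Without treatment IFIT3, OAS2 and CMPK2 were already higher and SAMD9 lower in knockout cells, at low levels in both genotypes. Untreated IFIT1 lay at 5.62 to 7.81 CPM in knockout and 2.05 to 2.57 in wild-type libraries, and ISG15 at 1.49 to 1.86 and 0.94 to 1.17. With IFNγ the IFIT1 ranges overlapped, at 3.38 to 4.24 and 4.04 to 5.71 CPM. IDO1 lay between 0.04 and 0.41 CPM in all untreated libraries. NLRC5, PSMB8, B2M and IFI16 were lower in untreated knockout cells, and NLRC5 was still lower with IFNγ (log2 fold change -0.27, or -0.16 with GC offsets). The list medians over members with more than 3 counts in every group were -0.24 for the interferon gamma response, -0.72 for type I genes and -0.20 for MHC class II, where the last did not pass over these members. The lists of the interferon gamma response (adjusted p = 0.0573), MHC class II (0.161), integrated stress response (0.29), hypoxia and glycolysis (0.312), immediate early and heat shock genes (0.174), mitosis (0.455) and checkpoint and NK ligands (0.317) were not past the threshold with an estimated correlation.

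NF-κB and cell death genes responded less, with TNFAIP3 at -2.30, RELB at -2.30, IL32 at -2.85, BIRC3 at -2.38, FAS at -1.37 and BCL2L14 at -3.71. The medians were -0.64 for NF-κB and -0.21 for cell death genes. Among cholesterol genes (median -0.36 over the 22 members with more than 3 counts in every group) INSIG1 stood at -1.45, HMGCS1 at -0.39 and TM7SF2 at -1.0. The integrated stress response list had a median of 0.30, with SLC7A11 at 1.41 and PSAT1 at 0.75, but DDIT4 at -1.21. Hypoxia and glycolysis genes had a median of -0.23, with ALDOC at -1.69, PFKFB4 at -1.18, EGLN3 at -1.44 and BNIP3 at -0.61.

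Of cell cycle genes, CDT1 (-1.11), LIG1 (-0.60), CCNE2 (-0.97) and ORC1 (-0.86) responded lower, with a DNA replication median of -0.29. The mitosis median was 0.14, with CENPA at 0.66, and the p53 target CDKN1A stood at -1.99. Immediate early and heat shock genes had a median of -0.45, with HSPA1A at -2.29, HSPA1B at -2.05, DNAJB1 at -1.76 and JUN at -0.62, against EGR1 at 2.82, DUSP6 at 1.52, ETV4 at 2.93 and ETV5 at 2.72. Checkpoint and NK ligands had a median of -0.026 and did not pass over these members (camera adjusted p = 0.1), with MICB at -1.0 and MICA at -1.43. SWI/SNF genes stood at -2.20 for SMARCA2 and 0.39 for BRD7.

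Other genes with a higher response were MYH15 (4.96), COL21A1 (4.17), L1TD1 (3.18), SNX19 (2.10), ZCCHC12 (1.66) and CCND2 (1.44). Those with a lower one were FN1 (-1.23), ACTA2 (-1.89), NGFR (-2.08), MYBPC1 (-1.02), GPNMB (-3.42) and SCN9A (-3.14).

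PBRM1 RNA in the knockout pool rose with IFNγ while it fell in wild-type cells (difference 0.73). If unedited cells that match the wild-type culture in every gene held the remaining RNA, no gene could lie below the PBRM1 ratio of the treated cells. Yet 137 of 10505 genes did by more than 2 SE, and 76 when 2 SE of the PBRM1 ratio are allowed for as well. This argues against unedited cells of that kind only. For unedited cells that drifted from the wild-type culture the test cannot decide, since drift can also lower single genes. Other scalings kept the difference, the lower at 0.61 (edgeR adjusted p = 6.33e-04). Without knockout IFNγ replicate 2 the rise was 0.26 (SE 0.06, edgeR adjusted p = 7.99e-04), so that library alone does not account for it. A response of the edited transcript remains a hypothesis that these counts leave untested, and a part played by unedited cells stays open.

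Knockout IFNγ replicate 2 stood apart from the other libraries of its group. Its deviation followed GC content across genes (Spearman's rho -0.795), which is consistent with a GC bias in that library, but GC trends were not confined to it, with 0.439 and -0.457 in wild-type IFNγ replicates 1 and 3. Library size alone is argued against, since the correlation gap was 0.00568 after thinning to 1 depth. A different IFNγ response of that culture stays open, with a rho of 0.102 between the deviation and the wild-type response, between the bounds set for it.

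Interferon target RNA was lower in treated knockout cells. If responding knockout cells matched wild-type cells, a smaller share of them would lower all strongly induced genes by 1 factor. Of 59 genes at least 64-fold higher in wild-type cells, however, 22% (13) lay higher by more than 2 SE and 25.4% (15) below -1. This argues against a smaller share as the only cause. It cannot exclude a smaller share together with other differences between the pools. Scaling is argued against by a type I median of -0.48 or lower under other scalings, and replicate 2 by a median of -0.40 without it (camera adjusted p = 2.12e-05). A lower response of part of the target genes may remain as the biological hypothesis, which drift between the pools cannot be separated from.

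Other groupings of the libraries were compared with the real ones. For each of the 4 pairwise comparisons 1 of 10 splits of the 6 libraries, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real counts in these fits of 6 libraries were 11442 and 8946 for IFNγ in wild-type and knockout cells and 7254 and 6527 for the knockout without and with IFNγ, and the highest other was 0. For the difference of responses 1 of 100 drawn regroupings of 200, the real one, gave as many calls (4413, highest other 3240). The other drawn regroupings mix the genotypes within a treatment, so they also break up the knockout effect. They do not test the difference of responses alone, and no conclusion about chance is drawn from them. A regrouping that was not drawn, which swaps the genotypes in 1 treatment, called 8259 genes, because it measures the knockout effects that both treatments hold.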

How the results depend on the processing

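No call of a list, or of a gene named by the rule or given in the text, changed direction under the settings run for it. The other called genes were not checked for this. DESeq2, limma-voom and fits of 2 groups were not run for lists. Whether more genes were higher or lower turned in every comparison under some scaling, filter or left-out library; a scaling moves all genes of a library alike, so such a turn does not test the balance. Plain library sizes, GC offsets and leaving out the long arm of chromosome 1 were chosen after seeing the data. With a required change of at least 2-fold the counts were, higher and lower, 1792 and 1419 for IFNγ in wild-type cells, 1586 and 1423 in knockout cells, 828 and 572 for the knockout untreated, 709 and 788 with IFNγ, and 323 and 587 for the difference, with 2060 and 644 genes shared by the IFNγ and the knockout contrasts, since it keeps fewer genes. Plain library sizes gave 1514 genes responding higher and a type I median of 0.51 in untreated cells (camera adjusted p = 0.0592). GC offsets gave 3083 responding lower and a class I median of -0.24 in treated cells (0.075). With an estimated correlation the medians were unchanged by construction, 21 calls of other lists were lost, and of 15 lead list results 5 calls were lost: interferon gamma response for the difference (-0.45, adjusted p = 0.0573) and in treated cells (-0.46, 0.114), class I in treated (-0.33, 0.395) and untreated cells (-0.33, 0.24), and type I in untreated cells (0.44, 0.155). Leaving out 1 library moved the genes responding higher between 1533 and 3162, the lowest without wild-type IFNγ replicate 2 (1563 without replicate 1). The cause was not tested beyond this. For genes given in the text or named by the rule, 547 pairs of a gene and a comparison were followed. Pooled over the 12 fits that each left out 1 library, 131 calls ended, 13 were added and 6419 results stayed the same, called or not. In 1 fit each over these pairs, DESeq2 ended 3 and added 2, and limma-voom ended 4 and added 2. Libraries sharing a replicate number did not deviate together (2 of 18 correlations above 0.1, range -0.21 to 0.20, and 1 of 12 libraries correlated best with its own number). The number as a replicate block left PBRM1 at -1.85 and -1.12, kept the 15 lead list results on their side of the threshold and ended 3 calls of named genes. Depth limits genes of few counts: 29 genes called for the difference had 3 or fewer counts in a group.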

Other observations

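The tests of ERK-induced genes and of the long arm of chromosome 1 were chosen after the result was seen, and the test of chromosome 3 before. With IFNγ, THBS1, a matrix protein gene, stood at 11.3 ± 0.336 CPM in wild-type and 374 ± 15.5 in knockout cells (SD, n = 3), and MMP2, a matrix protease gene, at 45.1 ± 2.70 and 152 ± 24.0. NUPR1, a stress-induced chromatin protein gene, stood at 40.8 ± 5.30 and 122 ± 36.6 CPM. The smooth muscle actin gene ACTA2 was higher in untreated knockout cells by 1.96 (SE 0.31) and not past the threshold with IFNγ (0.07, SE 0.11).

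In treated knockout cells 4 genes that growth factors induce were higher, EGR1 at 4.01 (SE 0.13), ETV5 at 2.20 (SE 0.12), ETV4 at 2.01 (SE 0.14) and DUSP6 at 1.36 (SE 0.09). A hypothesis is that genes induced by the ERK pathway were higher as a group. The list of ERK feedback genes without these 4 had a median of 0.46, with 8 of 19 higher and 3 lower (camera p = 0.0343, or 0.0739 with an estimated correlation), so the call rests on the preset correlation. The result is consistent with the hypothesis, which was formed on the same data.

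The long arm of chromosome 1 was lower in knockout cells by a median log2 fold change of -0.54 untreated and -0.41 with IFNγ, ratios of 0.686 and 0.751. A different copy number of the arm in part of a culture may account for it, since 90.1% and 83.3% of its genes lay under 0. GC content is argued against, as the median was -0.54 with GC offsets. No DNA was measured, and whether such a change came with the editing or by drift is open.

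Loss of the end of chromosome 3 that takes PBRM1 with it could lower PBRM1 RNA without an edit within the gene, and would lower the genes beyond it too. The 309 tested genes telomeric of PBRM1 had a median log2 fold change of -0.060 (SE 0.013 over 1000 bootstrap draws) in untreated knockout cells, against -0.014 on the rest of the chromosome, which argues against a loss in a large share of the cells.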
